A study of Mus musculus with 8 samples.

How the data were processed

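The series profiled mouse gut sections with microDBiT, a spatial assay in which a pair of crossed microfluidic chips, each with 50 channels, writes a barcode onto the RNA of every crossing point (a spot), so that mouse and bacterial RNA are read from the same grid. Per the labels' protocols, bacterial RNA was given a poly(A) tail in the fixed section, and reverse transcription used a mixture of oligo-dT and random hexamer primers, which can prime on any RNA and also on leftover DNA. Of the 8 samples in the series, 7 were used; the sample labelled Intmix was not analysed here. The groups were taken from the sample titles and each has 1 library: CMM, CMS, ColonGF, Colonmix, SPF and SPFIBD from colon and IntGF from intestine. All carry the label of no treatment. GF and SPF are conventional abbreviations for germ-free and specific pathogen-free mice, which the labels do not expand; the other titles were used as names only.

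The values deposited by the authors are whole-number counts per feature and spot, with no normalization (none was negative or fractional). The genome build was GRCm38, per the submitters' processing notes; the aligner, the counting program, the gene annotation and any use of molecular identifiers or strand are not given in the sources used here. Features with a locus tag (a prefix, _RS and a number) were read as bacterial and all others as mouse. The files do not pair bacterial locus tags with gene or organism names, so bacterial features are described by prefix. A first set of 22 prefixes (38550 features with counts) occurred in CMM, CMS, ColonGF, Colonmix and IntGF, a second set of 16 prefixes (3966 features) in SPF and SPFIBD, and 0 were shared, so bacterial composition was compared only within a set. Mouse symbols were matched to a RefSeq gene table of GRCm38.p6, used for gene types, synonyms and lengths only; 96.7% to 97.5% of the mouse features of a library were matched.

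The files held 2485 (CMM), 2488 (CMS), 2496 (ColonGF), 2500 (Colonmix), 2500 (IntGF), 2498 (SPF) and 2493 (SPFIBD) of the 2500 grid positions. Spots with at least 100 counts were kept (2353 to 2493 per library, with 99.9% to 100% of the counts), and no doublet caller was run on spots. Total counts were 5706978 for CMM, 5666237 for CMS, 5053160 for ColonGF, 13403200 for Colonmix, 12827013 for IntGF, 13491638 for SPF and 7903615 for SPFIBD.

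With 1 library per group there is no test between groups, and no p-value or standard deviation is given. Counts were summed over the kept spots and scaled with TMM factors (edgeR 4.0.16, used for scaling only, in R 4.3.3) over the 7 libraries. Each gene with at least 100 counts over a pair of libraries was given a log2 ratio with an exact (conditional binomial, Clopper-Pearson) 95% interval. Such intervals, and those of shares, cover counting error only: reads copied by PCR are not independent molecules, and differences between mice, sections and library preparations are not in them. A gene was counted as higher or lower where its ratio was at least 2-fold and its interval excluded equality. Ratios are printed relative to the median of all tested genes of the comparison, since scalings moved that median by more than 0.1. A gene at 0 is given as a bound against 3 counts. For gene lists, fixed from textbook markers and pathways, the median ratio of the members with at least 100 counts (5 or more needed) was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list outside the central 95% is called apart, as a description of these libraries. Genes named in a comparison are the 8 highest and 8 lowest with at least 50 CPM in the higher library that were at least 1.5-fold apart in the same direction in every pairing of the lower and upper parts of the sections (ribosomal RNA repeats, ribosomal protein and mitochondrial genes and unnamed gene models excluded), and up to 4 members of each list with the largest absolute ratio. For each library they are the 10 genes with the highest Moran's I and the 5 leading genes of the 4 largest regions. These choices were made before the data were examined. Features and prefixes outside this rule that are named below were chosen after their values were seen.

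Spatial pattern was measured by Moran's I over the 4 adjacent spots, on ln(1 + counts scaled to the library's median spot total), for the 1000 features with most counts in each section; a feature was called patterned at an I of at least 0.05 that exceeded its highest value in 100 permutations of the spots. Regions were found with scanpy 1.11.5 and igraph 0.11.9: 2000 variable genes, 20 principal components, 15 nearest neighbours and Leiden clustering at resolution 0.5, with clusters under 20 spots counted apart. Regions are described by their leading genes and not as cell types. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and scikit-image 0.26.0, and figures matplotlib 3.10.9.

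The procedures were tested on simulated data. Counts were Poisson draws with known library sizes and no trend with gene length, and simulated sections had no channel or depth differences. The results below therefore cover counting error only, and not the other differences between these libraries. For SPFIBD over SPF (10229 genes), 100 of 200 genes set 2-fold apart, 182 of 200 set 3-fold apart and 183 of 200 set 4-fold apart were counted as apart, 2 genes were when none was set, and 95.7% to 95.9% of the intervals covered the true ratio. Of 200 random lists, 11 fell outside the central 95%. In the SPFIBD section, 0 of 500 features without a pattern and 100 of 100 with one were called.

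Alternatives fixed beforehand were counts per library total without a factor (CPM), DESeq2 1.42.0 size factors, CPM without mitochondrial, ribosomal protein and ribosomal RNA repeat genes, other spot filters, odd or even channels, the lower or upper part of the section, a thinned deeper library, count minimums of 300 or 20, and, for patterns and regions, other neighbours, thinning to 500 counts per spot, channel means removed, raw counts, a higher minimum of I, other resolutions, components and gene sets. Alternatives chosen after seeing the data were removal of the trend with gene length, random lists matched also on gene length or matched on counts per kb in the second library, features with a count in both libraries, the bacterial share outside the 20 largest mouse features, bacterial prefixes without their largest feature, and lists in spots of high bacterial share without their largest member.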

Results

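Mouse and bacterial features were counted over grids of spots laid on sections of colon (CMM, CMS, ColonGF, Colonmix, SPF and SPFIBD) and intestine (IntGF), with 1 library per group and no replicates. Whether bacterial counts came from RNA or from leftover DNA was not tested. The comparisons set tissue against tissue among the libraries labelled GF, CMM against CMS, SPFIBD against SPF, and SPF and Colonmix each against ColonGF. Each difference is between the 2 libraries named and has no replicate check; intervals in parentheses are 95% and cover counting error only. The median kept spot held 2004.5 counts in CMM, 2103 in CMS, 1595 in ColonGF, 4903 in Colonmix, 4100 in IntGF, 4824.5 in SPF and 2886.5 in SPFIBD. A few features took most mouse counts, since the 10 largest held 55.2% in CMM, 55.4% in CMS, 56.0% in ColonGF, 74.7% in Colonmix, 82.4% in IntGF, 80.6% in SPF and 52.0% in SPFIBD. Rn18s-rs5, a ribosomal RNA repeat, was the largest feature of CMM, CMS, Colonmix, IntGF and SPFIBD, Cmss1 that of SPF and LOC118568312 that of ColonGF.

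The ColonGF file lacks counts on features that all other files hold, whether through another annotation or another assignment of reads is not known. It held counts for 0 of the 13 mitochondrially encoded protein genes and had 0 counts of Rn18s-rs5, whereas each other library had counts for all 13. It listed 431 pseudogenes against 2998 to 7294 elsewhere. Ratios of mitochondrial, ribosomal RNA and tRNA features against ColonGF are therefore left aside, as are Cmss1 (2 counts in ColonGF against 1410712 in IntGF, 2072203 in Colonmix and 4201394 in SPF) and Cdk8 (55 against 1306190, 832896 and 960408). Counts also followed gene length to differing degrees. Across protein-coding genes, which are not independent replicates, the Spearman correlation of counts with gene length was 0.883 in CMM, 0.885 in CMS, 0.821 in Colonmix and 0.842 in SPFIBD, but 0.530 in SPF, 0.305 in IntGF and 0.152 in ColonGF. Long genes were higher where the libraries of a comparison differed in this: the log2 ratio correlated with length at 0.76 for Colonmix over ColonGF, 0.75 for SPF over ColonGF, 0.49 for SPFIBD over SPF, 0.21 for IntGF over ColonGF and 0.01 for CMM over CMS. List ranks are therefore also given among random lists matched on counts per kb in the second library, an alternative chosen after seeing the data.

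**Figure D1:**
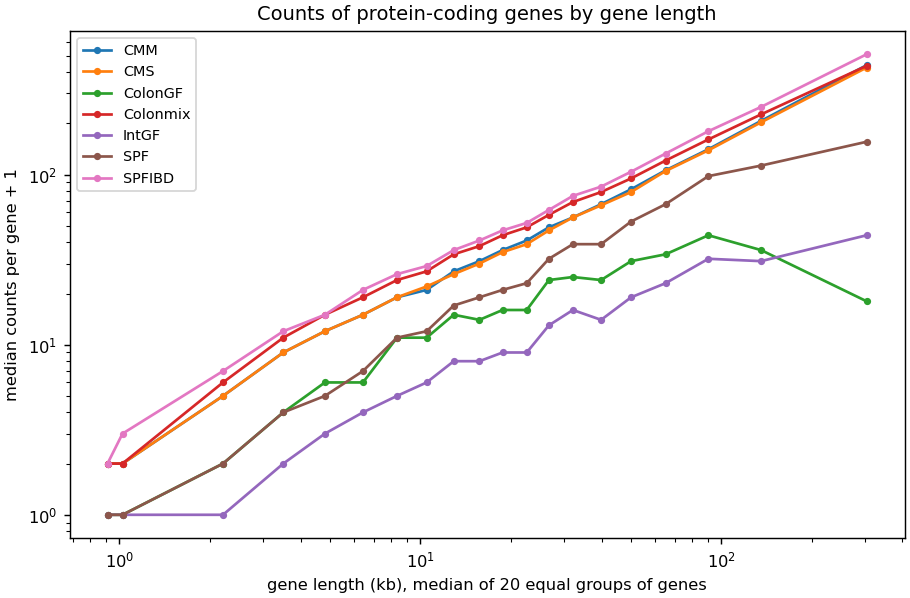
Median counts per protein-coding gene plus 1 (log axis) against gene length in kb (log axis), for 20 equal groups of genes in each of the 7 libraries; each line is a library. CMM, CMS, Colonmix and SPFIBD climb steadily with length, whereas ColonGF, with a Spearman correlation of 0.152, stays far flatter over the longer genes.

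Intestine and colon of the libraries labelled GF differed in the genes of their absorptive and Paneth cells. All 18 measured small-intestinal enterocyte genes were higher in IntGF, among them the ileal bile acid carrier Fabp6 (log2 ratio 12.22, 10.67 to 14.50; 8779 against 3 counts), the lipoprotein gene Apoa1 (10.85, 9.62 to 12.47), Mttp, which loads lipid onto lipoproteins (8.31, 6.95 to 10.19), and the brush-border peptidase Anpep (7.77, 7.37 to 8.20). All 7 Paneth cell genes measured were higher, with Lyz1 at 6.49 (5.35 to 7.95) and Defa20, an antimicrobial defensin, at least 129-fold higher (237 against 0 counts). Defensin genes are near-identical copies, so single members are uncertain. The colonic carbonic anhydrase Car1 was lower in IntGF (-9.65, -14.95 to -7.17; 1 against 1305 counts), as was the water channel Aqp4 (-7.65, -12.96 to -5.17). Aqp8 (0 against 470 counts) was at least 96.2-fold lower. The median of all tested genes was 0.19 and values are relative to it.

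Of 17 absorptive colonocyte genes, 9 were lower and 4 higher in IntGF (median -1.19), the latter including Guca2b (5.81, 5.20 to 6.49). Muc2, the main secreted mucin, was lower (-2.91, -2.94 to -2.88) and the mucus lectin Zg16 higher (1.43; 4039 against 2438 counts), with 6 of 14 goblet cell genes lower and 1 higher. Among 12 epithelial antimicrobial genes 6 were lower, led by Saa1 (-7.84, -9.16 to -6.80) and the amino acid carrier Slc6a14 (-4.85, -5.73 to -4.09), and 3 higher, led by the lectin Reg3g (7.10, 5.86 to 8.73). Fibroblast and matrix genes were lower in 16 of 17 (median -1.67; Dpt -3.50, -4.39 to -2.72; Col3a1 -2.63, -2.80 to -2.46). Smooth muscle genes were lower in 10 of 15 (median -1.26; Cnn1 -2.42, -2.80 to -2.06; Actg2 -1.85, -2.12 to -1.59). Crypt stem and progenitor genes were lower in 6 of 10 with 1 higher (median -1.43; Ephb3 -2.76, -3.80 to -1.87; Slc12a2 -2.12, -2.41 to -1.84). Cholesterol synthesis genes were higher in 10 of 18 (median 1.11), including Sqle (2.28, 2.02 to 2.55) and Cyp51 (1.40, 1.09 to 1.71). Srebf2, the transcription factor that drives them, was the member that was lower (-3.83, -4.01 to -3.65). Of 8 interferon-response genes 3 were higher and 1 lower (median 0.74; Oasl2 1.33, 0.85 to 1.82), and the MHC class II chain Cd74 was at 1.04 (0.83 to 1.26). Other genes chosen by size were Dmbt1, a mucosal scavenger receptor (-5.12, -5.34 to -4.90), and B3gnt7 (-5.32, -6.32 to -4.47), both lower in IntGF.

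By rank, the enterocyte (percentile 100) and cholesterol lists (99.98) stood at the high end of 10000 random lists. The colonocyte, goblet, antimicrobial, crypt, smooth muscle, fibroblast and oxidative phosphorylation lists stood at 0.53 or under. With matching on counts per kb the goblet list moved to 8.20, oxidative phosphorylation from 0.07 to 12.9, the interferon-response list from 97.09 to 99.21 and the Paneth list from 96.46 to 97.8. Of 5898 genes, 1341 were at least 2-fold higher and 784 lower. CPM without a factor gave 311 and 4838, CPM without mitochondrial, ribosomal protein and ribosomal RNA repeat genes 398 and 3503, and removal of the length trend 1027 and 943. Relative to the median, 1116 were higher and 980 lower. Of 23 nuclear-encoded oxidative phosphorylation genes 5 were lower and 1 higher. Lists not apart in the main ranking had 2 of 17 fatty acid oxidation genes lower and 1 higher, 4 of 14 immediate early and heat shock genes lower, 2 of 5 enteroendocrine genes lower and 1 higher, and 3 of 5 adipocyte genes lower and 2 higher.

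CMM and CMS were close to each other, with few genes at least 2-fold apart, among them mucus and colonocyte genes. Muc2 was 4.1-fold lower in CMM (log2 ratio -2.03, -2.13 to -1.94; 1232 against 4903 counts). Guca2a, the guanylin of goblet and surface cells, was lower too (-2.46, -2.93 to -2.02), as were, by less, the cytochrome Cyp2c55 (-1.07, -1.47 to -0.69) and Car1 (-1.03, -1.38 to -0.69). The tRNA feature n-TRtct2 (-1.09, -1.24 to -0.93) is uncertain, having near-identical copies. Zg16 went the other way without reaching 2-fold (0.39, 0.24 to 0.55). Of 16 absorptive colonocyte genes 4 were lower and 0 higher (median -0.35, percentile 0), and of 11 goblet cell genes 2 were lower (median -0.15, percentile 0.68, or 9.67 with matching on counts per kb, and 79.6 in the upper part of the section). The 13 mitochondrially encoded genes had a median of -0.28 (percentile 0), with ND5 at -0.52 (-0.59 to -0.46) and CYTB at -0.44 (-0.51 to -0.37), none of them 2-fold apart. With random lists matched on gene length, absorptive genes stayed at percentile 0, goblet cell genes moved to 3.81 and mitochondrially encoded genes to 5.42. Over all 10530 genes, 1 was higher and 15 lower, the median was -0.01, and no further list with 5 or more members measured fell outside the central 95%. Spearman's correlation of counts across 8403 protein-coding genes was 0.952. It is a weak measure of closeness, since counts of both libraries followed gene length (0.883 and 0.885). With SPFIBD, which shares that trend, the correlation was 0.903 for CMM and 0.914 for CMS.

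Relative to all tested genes, SPFIBD was lower than SPF in muscle genes and, by less, in surface epithelium and connective tissue genes. Smooth muscle genes were lower in 15 of 16 (median -2.56), including the intermediate filament gene Synm (-3.66, -3.96 to -3.37), smooth muscle actin Acta2 (-3.38, -3.63 to -3.15), the myosin Myh11 (-3.32, -3.45 to -3.19), Tpm2 (-3.31, -3.56 to -3.06) and Tpm1 (-3.27, -3.45 to -3.09). Absorptive colonocyte genes were lower in 13 of 16 (median -1.47), with the surface mucin Muc3 at -2.86 (-2.93 to -2.79), the chloride exchanger Slc26a3 at -2.26 (-2.47 to -2.06) and Car1 at -2.08 (-2.27 to -1.90). Fibroblast and matrix genes were lower in 12 of 17 (median -1.24; Dcn -2.09, -2.48 to -1.70; Col6a1 -1.78, -2.05 to -1.51). The median of all tested genes was -0.71 and values are relative to it. By CPM that median was 1.45, so these values do not give absolute transcript levels.

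Muc2 was lower too (-2.36, -2.39 to -2.33; 9614 against 30518 counts), with 6 of 14 goblet cell genes lower and none higher, and 4 of 10 epithelial antimicrobial genes were lower, among them Pigr, which carries antibody across the epithelium (-1.89; 991 against 2266 counts). All 6 immediate early and heat shock genes measured were lower (median -1.62; Hsp90aa1 -2.52, -3.01 to -2.05; Jun -1.75, -2.22 to -1.30). Higher in SPFIBD was the antibody heavy chain gene Igha (1.32; 2836 against 704 counts), whose constant region is shared in part with other antibody genes. Of 6 MHC class II genes, Ciita, the master regulator of that group, was higher (1.24, 0.76 to 1.75) and Cd74 (-0.43, -0.67 to -0.20) and H2-Ab1 (-0.62, -0.93 to -0.31) were under 2-fold apart. Of 6 macrophage and dendritic cell genes 1 was higher, the complement gene C1qb (1.25, 0.67 to 1.87), and 1 lower. Neutrophil and inflammatory cytokine genes were near the detection limit: 1 neutrophil gene, Ly6g (0.82, 0.20 to 1.49), and 2 cytokine and NF-kB genes reached 100 counts over both libraries. A difference in these groups was not detectable at this depth.

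By rank, the smooth muscle, absorptive, fibroblast and immediate early lists were all at percentile 0, oxidative phosphorylation at 0.01 and fatty acid oxidation at 0.11. Matched on counts per kb, smooth muscle stayed at 0, absorptive genes at 0.41 and fibroblast genes at 1.38. Relative to the medians of the matched random lists, these 3 lists were at -1.55, -0.47 and -0.33. The absorptive and fibroblast lists were thus under 2-fold lower than genes of like counts per kb. Immediate early genes moved to 4.57, fatty acid oxidation to 12.6 and oxidative phosphorylation to 66.7. MHC class II genes moved from 64.4 to 99.1 and mitochondrially encoded genes from 83.2 to 100. The goblet (percentile 8.98, or 92.5 with counts per kb matched) and antimicrobial lists (2.80, or 57.3) were not apart by either ranking. Nor, in the main ranking, were the small-intestinal enterocyte (3 higher and 3 lower of 9), crypt (2 and 2 of 12), endothelial (2 higher of 12), enteric neuron and glia (3 higher of 7), interstitial cell of Cajal (1 and 1 of 6), interferon-response (none of 5) and cholesterol (1 lower of 14) genes. Among genes chosen by size, the nuclear RNA Malat1 was lower (-3.56, -3.63 to -3.49), as were Kcnip1 and Cmss1 (-5.08 and -4.94; 162221 and 4201394 counts in SPF), which held so many counts in SPF that their values are uncertain. Very long genes were higher, such as Spag16 (3.35, 2.97 to 3.75), Gpc5 (3.17, 2.89 to 3.47), Erbb4 (3.10, 2.75 to 3.47) and Dcc (1065 against 82 counts); Spag16 was at 1.96 once the length trend was removed. Of 10229 genes, 1951 were higher and 4045 lower, against 6850 and 48 by CPM, 2374 and 2515 by DESeq2 size factors, 6070 and 64 without mitochondrial, ribosomal protein and ribosomal RNA repeat genes, and 2306 and 1495 with the length trend removed. Relative to the median, 2834 were higher and 1343 lower.

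**Figure D2:**
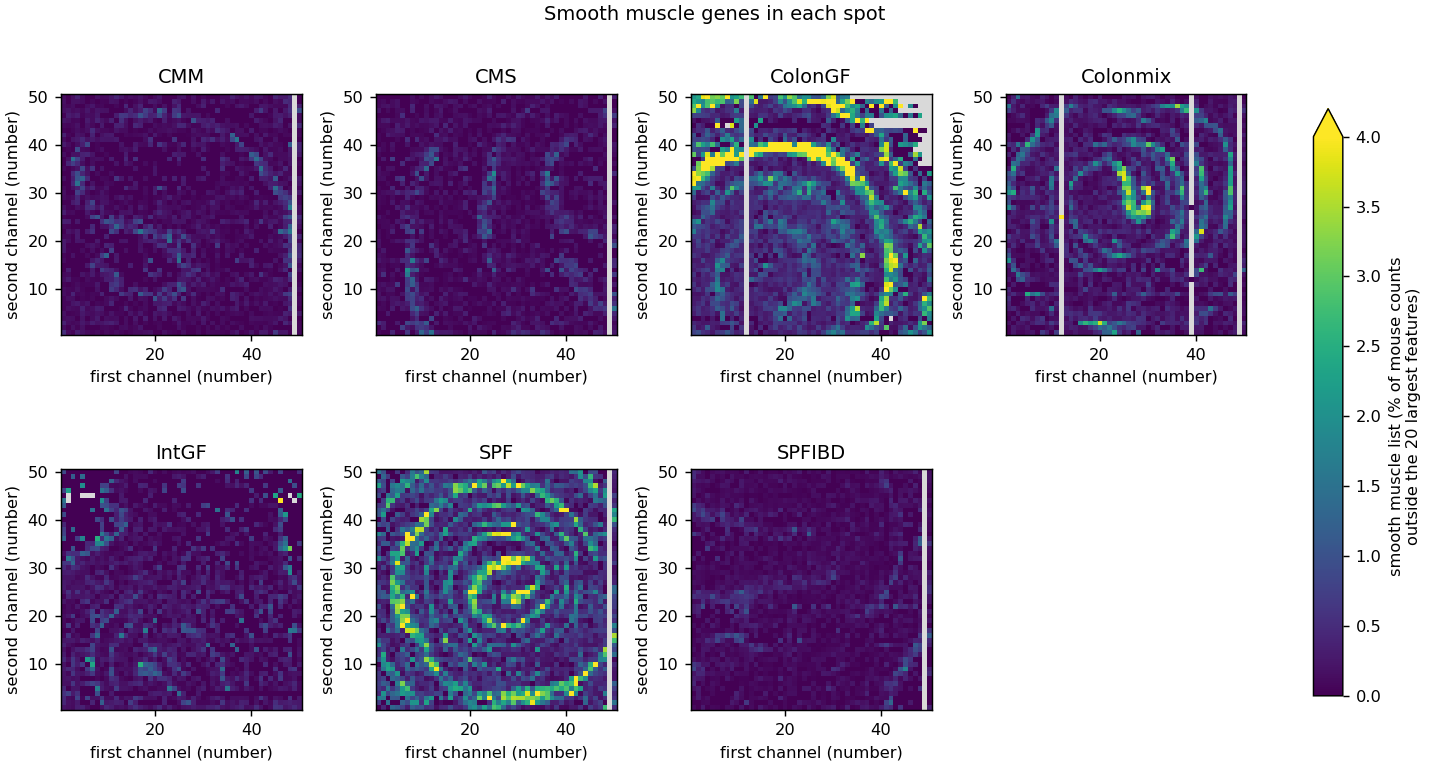
Share of the smooth muscle list in the mouse counts outside the 20 largest features (%, colour), for every spot of the 7 sections; axes are channel numbers and grey marks positions left out. SPF and ColonGF show bright bands, spiral in SPF, and SPFIBD shows only faint arcs, beside a median log2 ratio of -2.56 for the list between SPFIBD and SPF.

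SPF over ColonGF sets a colon section of the library labelled SPF against one labelled GF, whose file lacks features as described. Smooth muscle genes were higher in SPF in 4 of 15 and lower in none (median 0.20), including Tpm2 (1.28, 1.11 to 1.45) and Synm (1.21, 1.03 to 1.39). Cholesterol synthesis genes were lower in 10 of 15 (median -1.40): Srebf2 (-4.54, -4.73 to -4.36), its partner Insig1 (-2.19, -2.65 to -1.75) and Hmgcs1 (-2.10, -2.41 to -1.80). Mucus genes were lower in 6 of 15, with the mucus protein Fcgbp at -3.31 (-3.38 to -3.24), Clca1 at -2.09 (-2.18 to -2.01) and Muc2 at -1.61 (-1.63 to -1.59). Of 7 small-intestinal enterocyte genes 5 were lower and 1 higher (median -1.18; Apob -2.35, -2.62 to -2.08). The median of all tested genes was -0.13 and values are relative to it.

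Also lower in SPF were 10 of 14 immediate early and heat shock genes (median -1.31; Egr1 -3.02, -3.67 to -2.43), 16 of 23 oxidative phosphorylation genes (median -1.18), 10 of 16 absorptive colonocyte genes with 1 higher, 4 of 16 fatty acid oxidation genes, 5 of 10 antimicrobial genes with 1 higher, 2 of 8 cell-cycle genes and 4 of 17 fibroblast genes. The cholesterol list was at percentile 0 and at 0.04 with matching on counts per kb, the enterocyte list at 2.10 and 0.38, and smooth muscle at 99.1 and 100. The remaining calls ended with that matching: oxidative phosphorylation moved from 0.01 to 49.5, immediate early genes from 0.04 to 43.2, absorptive genes from 1.76 to 33.4 and fatty acid oxidation from 1.17 to 20.4. Goblet (percentile 21.9, or 90.6 with that matching), fibroblast (41.3, or 94.0), cell-cycle (3.06, or 15.1) and antimicrobial genes (2.56, or 23.55) were not apart by either ranking. Nor were crypt (3 higher and 1 lower of 11), endothelial (2 higher of 6), interstitial cell of Cajal (2 higher and 1 lower of 6) and macrophage genes (2 lower of 5). Outside the tRNA features, the lowest genes were Washc1 (-6.97, -7.48 to -6.51) and Adgrb2 (-6.59, -7.32 to -5.94), both uncertain given how ColonGF differs from the other files. Of 7154 genes, 1596 were higher and 1713 lower, against 665 and 4455 by CPM, 1242 and 2463 by DESeq2 size factors and 835 and 3445 without mitochondrial, ribosomal protein and ribosomal RNA repeat genes. Relative to the median, 1747 were higher and 1422 lower, and with the length trend removed 1003 and 811, so the balance depends on the scaling.

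Colonmix over ColonGF showed lower metabolic genes in Colonmix. Cholesterol synthesis genes were lower in 14 of 17 (median -2.25), including Srebf2 (-5.30, -5.49 to -5.12), Hmgcs1 (-3.48, -3.86 to -3.12), the cholesterol carrier Stard4 (-3.21, -3.59 to -2.86) and Insig1 (-3.21, -3.73 to -2.73). Both this comparison and SPF over ColonGF rest on the same ColonGF library, where Srebf2 had 6199 counts, against 251 in Colonmix, 260 in SPF and 268 in IntGF. Fatty acid oxidation genes were lower in 16 of 17 (median -2.01), including Eci1 (-3.30, -3.77 to -2.86) and Acadvl (-2.80, -3.23 to -2.39). Small-intestinal enterocyte genes were lower in 6 of 8 with 1 higher (median -1.93; Apob -3.37, -3.67 to -3.07) and goblet cell genes in 11 of 15 (median -2.63; Fcgbp -4.86, -4.95 to -4.77; Muc2 -4.36, -4.39 to -4.33). The median of all tested genes was -0.57 and values are relative to it.

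Lower in Colonmix were also 15 of 16 absorptive colonocyte genes (median -2.60), 23 of 23 oxidative phosphorylation genes (median -2.59), 14 of 16 immediate early and heat shock genes (median -2.27; Egr1 -3.57, -4.19 to -3.01), 6 of 7 cell-cycle genes, 13 of 17 fibroblast genes, 4 of 5 enteroendocrine genes and 4 of 6 adipocyte genes with 1 higher. Smooth muscle genes were lower in 6 of 16 and higher in 1 (median -0.74), with Acta2 at -1.37 (-1.52 to -1.23) and Myl9 at -1.66 (-1.85 to -1.47), the latter 0.12 once the length trend was removed. With matching on counts per kb, cholesterol (0.03), enterocyte (0.04), fatty acid oxidation (0.20), goblet (1.83) and absorptive genes (1.89) stayed at the low end. With the length trend removed, lists apart numbered 6 in place of 9: cholesterol (0.07), enterocyte (0.01) and fatty acid oxidation genes (0.72) stayed low, whereas goblet cell genes moved to 29.2 and absorptive genes to 65.5. Oxidative phosphorylation moved from 0 to 3.39, cell-cycle genes from 1.21 to 23.3 and immediate early genes from 0 to 92.9. Smooth muscle moved from 93.8 to 100 and MHC class II from 21.8 to 97.8. Antimicrobial (7 lower and 1 higher of 11), crypt (5 higher and 3 lower of 12), endothelial (4 higher and 2 lower of 9), enteric neuron and glia (6 higher of 6), interstitial cell of Cajal (2 higher and 3 lower of 7), macrophage (1 higher and 3 lower of 6), MHC class II (2 higher and 2 lower of 6) and interferon-response genes (1 lower of 6) were not apart in the main ranking. Washc1 was the lowest named gene (-7.37). Of 9528 genes, 2844 were higher and 3997 lower, against 3355 and 2861 without mitochondrial, ribosomal protein and ribosomal RNA repeat genes and 2510 and 2226 with the length trend removed. Relative to the median, 3404 were higher and 2938 lower, so here too the balance depends on the scaling.

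**Figure D3:**
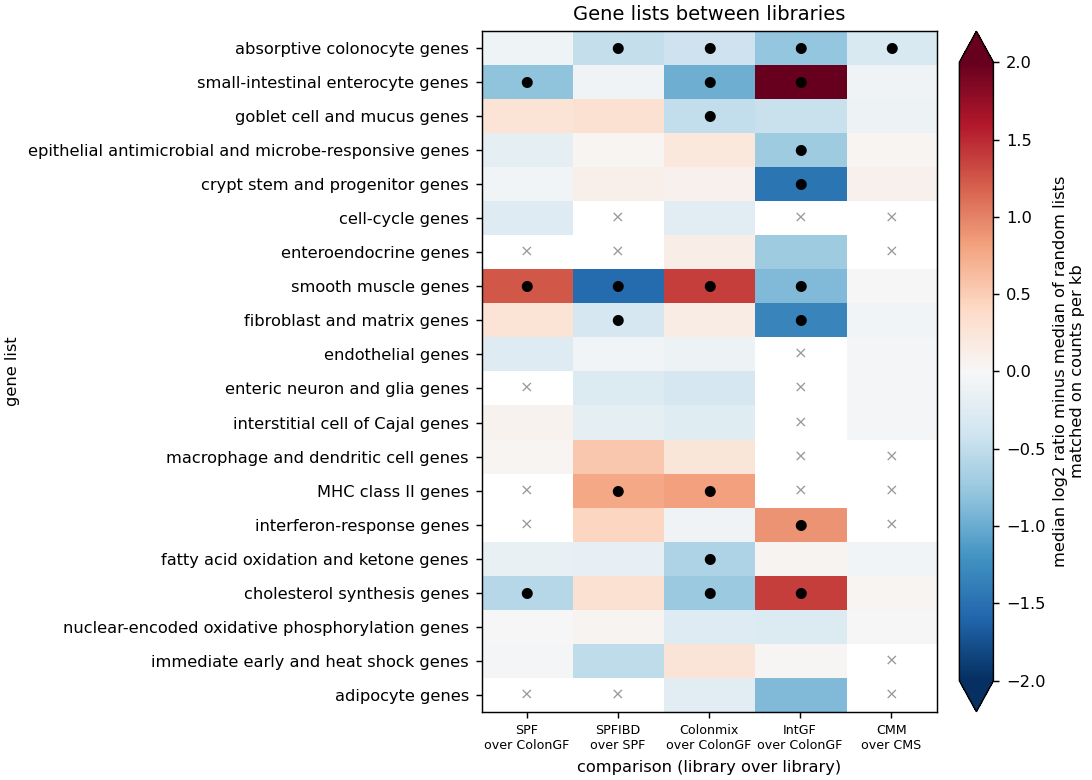
Median log2 ratio of each gene list minus the median of random lists matched on counts per kb in the second library (colour, limited at -2.0 and 2.0), for the 5 comparisons; dots mark lists outside the central 95% of 10000 random lists and crosses lists with under 5 members measured. Relative to those random lists, smooth muscle genes are low in SPFIBD over SPF and high in SPF and Colonmix over ColonGF. Cholesterol synthesis genes are low in SPF and Colonmix over ColonGF.

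Bacterial features held 3.61% (3.60 to 3.63) of counts in CMM, 4.46% (4.44 to 4.47) in CMS, 1.75% (1.75 to 1.76) in Colonmix, 2.06% (2.06 to 2.07) in SPF and 1.22% (1.21 to 1.22) in SPFIBD, with exact intervals. The libraries labelled GF, which serve as background for the first set of prefixes, had 0.0279% (0.0264 to 0.0294; 1407 counts) in ColonGF and 0.00866% (0.00816 to 0.00919; 1111 counts) in IntGF. Bacterial counts were found in 100% of the spots of CMM, CMS, Colonmix and SPF, in 99.8% of those of SPFIBD, in 40.9% of ColonGF and in 30.6% of IntGF. The median spot held 52 bacterial counts in CMM, 65 in CMS, 75 in Colonmix, 67 in SPF, 28 in SPFIBD and 0 in ColonGF and IntGF. Relative to ColonGF the share was 62.9-fold higher in Colonmix (59.7 to 66.3), 129.6-fold in CMM (123.0 to 136.7) and 159.9-fold in CMS (151.7 to 168.6). Outside the 20 largest mouse features, which take differing parts of the libraries, these were 113.7, 114.9 and 141.4. CMM was 1.23-fold lower than CMS (1.23 to 1.24). SPFIBD was 1.70-fold lower than SPF (1.68 to 1.71), and 4.79-fold lower (4.75 to 4.82) outside the 20 largest mouse features.

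The prefix Bovatus held the largest part of the bacterial counts in CMM (40.1%), CMS (39.7%) and Colonmix (33.1%), followed by K6V30 (19.6%, 16.5% and 16.0%). Between CMM and CMS, which had similar profiles, GOZ73 was lower in CMM (1.93% against 3.94%; log2 ratio of shares -1.03, -1.08 to -0.98), as were CDL20 (-0.77, -0.84 to -0.70) and Fi14EGH31 (-0.63, -0.71 to -0.54). Of their features with at least 50 counts, 3 of 8, 2 of 2 and 4 of 18 were lower. Colonmix had more of C4Q21 (3.63, 3.36 to 3.91, or 2.35 without its largest feature), LUA64 (2.60, 2.49 to 2.71), CSV91 (2.17, 2.03 to 2.32), ENT (1.46, 1.38 to 1.55) and RY69 (1.32, 1.26 to 1.39) than CMS, and less of CDL20 (-1.12, -1.20 to -1.05), although of its 2 features with at least 50 counts 1 was higher and 0 lower. In SPF the largest prefixes were DY261 (21.3%), GN277 (19.3%), RGna (16.3%), ARA08 (13.6%) and KDJ91 (10.3%). SPFIBD had more of C5O23 (2.85% against 0.493%; 2.53, 2.44 to 2.62), EZ315 (1.83, 1.75 to 1.91), F8244 (1.47, 1.42 to 1.51; 49.5% of its counts were in 1 feature, and the ratio without it was 1.65) and OCV80 (0.95, 0.91 to 0.99), and less of RGna (8.39% against 16.3%; -0.96, -0.99 to -0.92) and DY261 (-0.45, -0.48 to -0.42). Single features of the latter pair more often went the other way: among those with at least 50 counts, 16 of 38 were higher and 8 lower for RGna, and 17 of 50 higher and 10 lower for DY261.

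**Figure D4:**
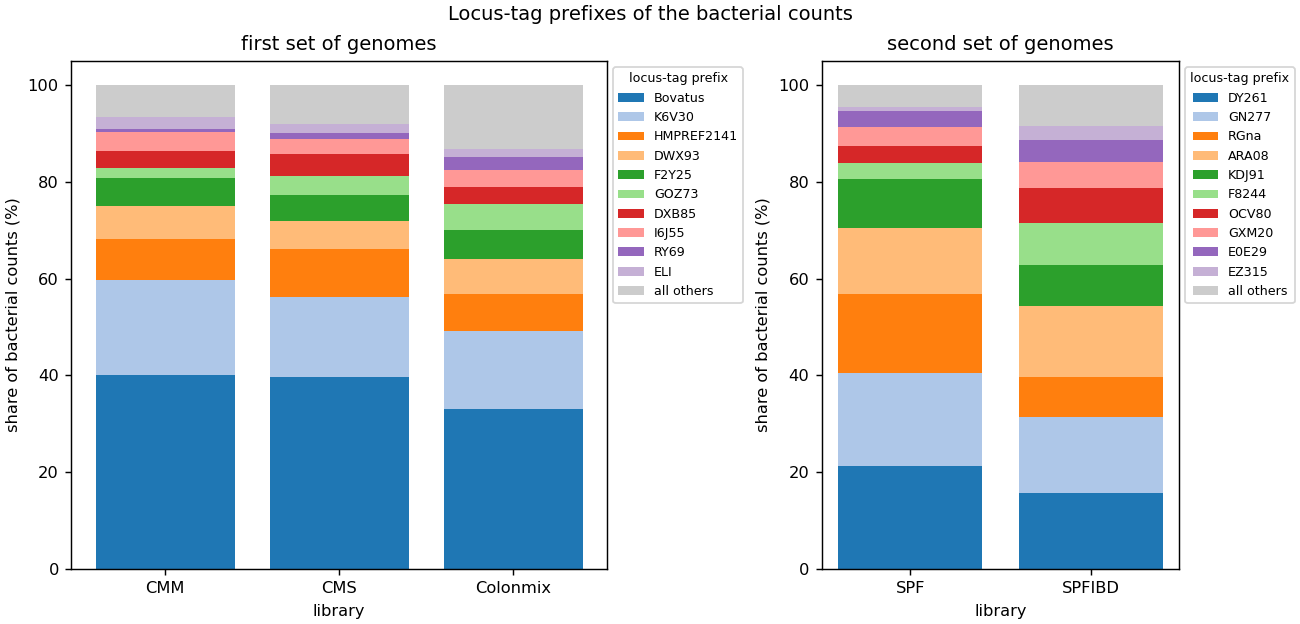
Share of the bacterial counts (%) held by each locus-tag prefix, stacked, for libraries counted on the first (left) and second (right) set of prefixes. Bovatus is the largest part of CMM, CMS and Colonmix, and RGna takes 16.3% in SPF and 8.39% in SPFIBD.

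Bacterial counts were unevenly spread over the sections. Moran's I of the bacterial share was 0.70 in CMM, 0.77 in CMS, 0.74 in Colonmix, 0.80 in SPF and 0.62 in SPFIBD, and 0.04 in ColonGF and 0.08 in IntGF. IntGF met the rule for a pattern (highest permutation 0.03) and ColonGF did not (0.05). With 1407 counts in ColonGF and 1111 in IntGF, so few counts limit I, and these libraries are no matched reference. Pooled over the 10% of spots with the highest share, the bacterial share was 18.2% in CMM, 19.3% in CMS, 6.83% in Colonmix, 15.3% in SPF and 5.92% in SPFIBD. The other spots held 2.60%, 3.19%, 1.49%, 1.46% and 0.966%. Spots chosen by their share differ in it by construction, so this gap is no evidence of a spatial pattern. ColonGF (0.174% against 0.0208%) and IntGF (0.0425% against 0.00579%) had such a gap too. On the maps the spots of highest share formed arcs in CMM, CMS, Colonmix and SPFIBD and arcs and corners in SPF. Most single prefixes were patterned as well, with an I of 0.66 for Bovatus in CMM, 0.72 in CMS and 0.71 in Colonmix, and of 0.77 for ARA08 and 0.74 for DY261 in SPF. DW767 in Colonmix was not (0.03), and with channel means removed EUAN (0.01) and EZ315 (0.02) in SPF and AQ990 (0.01) in Colonmix were among the prefixes that fell under their permutations.

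**Figure D5:**
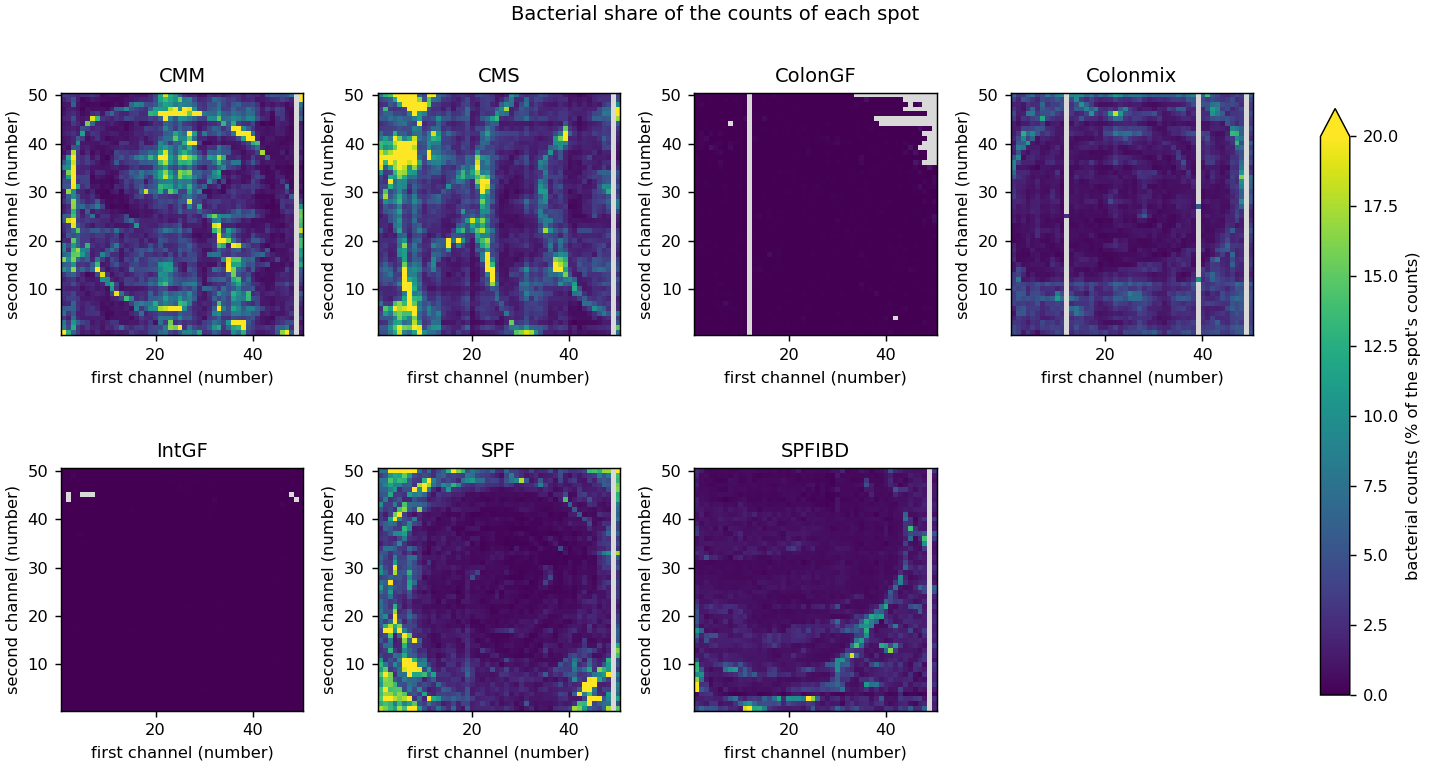
Bacterial share of the counts of each spot (%, colour, limited at 20%) in the 7 sections; axes are channel numbers and grey marks positions left out. The share gathers in arcs and corners in CMM, CMS, Colonmix, SPF and SPFIBD (Moran's I from 0.62 to 0.80) and is near 0 throughout ColonGF and IntGF.

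Mouse genes were also patterned, including muscle and mucus genes. Of 13 smooth muscle genes among the 1000 features with most counts in ColonGF all 13 were patterned (Myh11 at 0.27), as were 13 of 14 in SPF (Myh11 at 0.22), 10 of 11 in Colonmix (Des at 0.20), 3 of 4 in SPFIBD (Myl9 at 0.15) and 3 of 6 in IntGF (Flna at 0.11), but 1 of 2 in CMM (Myh11 at 0.06) and 0 of 1 in CMS. Mitochondrially encoded genes were patterned in 12 of 12 in CMM, CMS and SPFIBD, 8 of 11 in Colonmix, 6 of 12 in SPF and 1 of 10 in IntGF. With channel means removed the leading gene of this list was at 0.03 in CMM, 0.01 in CMS, -0.03 in Colonmix, 0.03 in IntGF and SPF and 0.09 in SPFIBD. The leading goblet cell gene was then at 0.32 in ColonGF, 0.22 in SPF, 0.16 in SPFIBD and 0.12 in Colonmix. It was at 0.10 in CMS, 0.049 in CMM and 0.048 in IntGF. The leading smooth muscle gene was then at 0.21 in ColonGF, 0.17 in SPF, 0.13 in Colonmix and 0.11 in SPFIBD. It was at 0.07 in IntGF, 0.03 in CMM and -0.03 in CMS. Before that removal, Muc2 had an I of 0.47 in ColonGF, 0.35 in SPF, 0.28 in CMS, 0.22 in SPFIBD and Colonmix and 0.13 in IntGF. Muc3 was at 0.35 in ColonGF. The leading goblet cell gene of CMM was Zg16 (0.09), and 1 of 4 goblet cell genes was patterned in CMS. In IntGF 10 of 17 enterocyte genes were patterned, led by Fabp6 (0.18), and in SPFIBD 3 of 4 fibroblast and matrix genes, led by Col3a1 (0.24), and 5 of 5 goblet cell genes. The genes with the highest I were mostly ribosomal RNA repeats and other features with very many counts, such as Rn18s-rs5 in CMM (0.69) and Cdk8 in SPF (0.73). Of 1000 features, 158 were patterned in CMM, 130 in CMS, 282 in ColonGF, 286 in Colonmix, 238 in IntGF, 156 in SPF and 305 in SPFIBD; with channel means removed these were 61, 35, 79, 36, 87, 67 and 147.

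Some regions of spots were led by muscle, surface or mucus genes. In ColonGF a region of 406 spots (17.2%) was led by Actg2 (log2 ratio to other spots 2.51, 2.30 to 2.71), Pdlim3, Myh11, Des and Acta2, with the smooth muscle list at 2.21 (2.16 to 2.26) and enteric neuron and glia genes at 1.08 (0.61 to 1.53). The largest region, of 754 spots, was led by Lama3, H2-Q2, Slc9a3 and Car4, with absorptive colonocyte genes at 0.93 (0.90 to 0.97) and smooth muscle genes at -1.05 (-1.10 to -0.99). A region of 593 spots led by Aqp1, Itga2 and Ccn3 had goblet cell genes at 0.91 (0.89 to 0.93) and cell-cycle genes at 0.77 (0.60 to 0.92). In Colonmix, 752 spots were led by Dcn, Acta2 and Tagln (smooth muscle list 0.79, 0.74 to 0.84). A further 625 were led by Muc3 (1.19, 1.10 to 1.29), 255 by Muc2 (1.55, 1.47 to 1.63) and 721 by the adhesion gene Chl1. The bacterial share was 1.23% (1.22 to 1.24) in the region led by Muc3 and 2.28% (2.27 to 2.30) in that led by Chl1. In IntGF, 1234 spots were led by Oat and other genes including Defa20 (1.31, 0.79 to 1.86), with Paneth cell genes at 0.92 (0.73 to 1.11). In SPF, 629 spots led by tRNA features had the smooth muscle list at 0.90 (0.85 to 0.94) and a bacterial share of 3.55% (3.53 to 3.58), against 1.32% (1.31 to 1.33) in 882 spots led by Ndufa6. SPFIBD regions were led by Selenom, Gm33838, Gm10925 and the mitochondrial ND1, and the largest regions of CMM and CMS mostly by single features such as ND2, TrnS1 and Chl1. There were 9 regions in CMM and in CMS, 4 in ColonGF, Colonmix and SPFIBD, 6 in IntGF and 3 in SPF. Some followed single channels: the busiest channel held 94.1% of the spots of the smallest region of CMM, 81.3% of that of CMS, 49.5% of a region of 99 spots in IntGF and 30.6% of the region led by ND1 in SPFIBD. The partition depended on the settings, with an adjusted Rand index to it of at most 0.601 under any alternative.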

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

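In CMM, Colonmix and ColonGF the spots under 100 counts, which were left out, held a larger bacterial share than the kept spots. This stood out because these counts lay outside the analysed spots. The share was 16.1% in Colonmix (15.1 to 17.1; 872 of 5427 counts in 147 spots), 9.47% in CMM (4.42 to 17.2; 9 of 95 counts) and 8.51% in CMS (3.75 to 16.1; 8 of 94 counts). The kept spots of these libraries held 1.75%, 3.61% and 4.46%, so the interval of CMS includes its kept share. In ColonGF the share was 0.194% (0.0971 to 0.348; 11 of 5659 counts), against 0.0279% in its kept spots. SPF, with 0.288% (1 of 347 counts), did not share the pattern, and IntGF and SPFIBD had 0 bacterial counts there. The kept spots hold 99.9% to 100% of the counts of each library.

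Counts followed gene length in CMM, CMS, Colonmix and SPFIBD. The tests of genomic DNA and of introns were set before their values were known, and that of the feature set was chosen after the result was seen. Olfactory receptor genes, which the gut hardly transcribes, serve to tell the explanations apart. In these libraries they held 0.564 to 0.725 times the counts per kb of the median protein-coding gene, so genomic DNA counted over gene bodies is a candidate explanation. The ratio is no proof of it, since it was 1.17 in IntGF, where counts follow length less and 9.91% of these genes had a count, against 63.6% to 78.3% in the libraries of the pattern. Among genes over 100 kb, those with the most ColonGF counts held 1.62 to 2.52 times the density of those with the fewest, a value by which a part from introns of transcribed genes cannot be told apart. Another feature set behind the ColonGF file cannot make the pattern, since ColonGF does not enter the correlation of counts with length within these libraries. SPFIBD over SPF, also without ColonGF, correlated with length at 0.487, a value already known. Whether a feature set adds to the correlations of Colonmix and SPF over ColonGF (0.76 and 0.75) was not tested.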

How the results depend on the processing

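Each group is a single library, so differences between mice, sections and preparations are not measured, and scaling, gene length and the features missing from ColonGF limit every comparison with that library. No paired analysis was possible because each group is 1 library and all share only the replicate number 1. Unless the setting itself leaves fewer genes or spots, the cause of a move was not tested.

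Genes at least 2-fold apart numbered 3309 for SPF over ColonGF, 5996 for SPFIBD over SPF, 6841 for Colonmix over ColonGF, 2125 for IntGF over ColonGF and 16 for CMM over CMS. With odd channels only, which leaves fewer genes, these were 2052, 2966, 3946 and 1291 for the first 4, and with even channels 1905, 3063, 3813 and 1224. The lower part of the second coordinate gave 2621 for SPFIBD over SPF, 4089 for Colonmix over ColonGF and 1406 for IntGF over ColonGF. The upper part gave 1738 for SPF over ColonGF, 3378, 3642 and 1106. A minimum of 300 counts gave 1411, 2187, 2623, 851 and 7, and a minimum of 20 counts gave 6876, 13302, 16484, 4869 and 486. CPM without a factor gave 5120 for SPF over ColonGF and 5149 for IntGF over ColonGF, and leaving out mitochondrial, ribosomal protein and ribosomal RNA repeat genes 3901 for the latter. Removing the trend with gene length gave 1814 for SPF over ColonGF and 3801 for SPFIBD over SPF.

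Lists apart numbered 8 of 16 for SPF over ColonGF. Odd channels gave 4, even channels 5, the lower part 5, the upper part 5, a minimum of 300 counts 4 and of 20 counts 13. Removal of the length trend, random lists matched on gene length and random lists matched on counts per kb gave 4 each. SPFIBD over SPF moved from 6 to 12 with a minimum of 20 counts and to 3 with length matching. CMM over CMS moved from 3 to 5 in the lower part and to 1 with length matching. Some list medians moved to the other side of the random median. In SPF over ColonGF the percentile of oxidative phosphorylation was 60.6 with the length trend removed, and in SPFIBD over SPF it was 66.7 with counts per kb matched. In Colonmix over ColonGF absorptive genes were at 65.5 with the trend removed, and immediate early genes at 63.6 with the trend removed, 56.8 with length matching and 92.9 with counts per kb matched. Goblet cell genes in CMM over CMS were at 79.6 in the upper part. Among named genes only Myl9 in Colonmix over ColonGF turned direction, at 0.12 with the length trend removed. The settings left 1174 of 1286 list results and 1095 of 1366 gene results unchanged, whereas 47 of 74 prefix ratios moved without the largest feature of the prefix and 29 of 42 counts of patterned features moved. The totals for lists and genes overstate stability. CPM and DESeq2 size factors shift all genes alike, so they cannot move values relative to the median, nor list ranks beyond the random draw. Lists that were not apart and stayed so also count as unchanged.

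Patterned features numbered 158 in CMM, 130 in CMS, 282 in ColonGF, 286 in Colonmix, 238 in IntGF, 156 in SPF and 305 in SPFIBD. In that order, removing channel means gave 61, 35, 79, 36, 87, 67 and 147, and thinning spots to 500 counts gave 47, 46, 82, 38, 53, 49 and 79. An I of at least 0.1 gave 76, 51, 110, 71, 114, 76 and 155, and raw counts gave 388, 361, 949, 541, 811, 516 and 796. With 8 neighbours CMS had 84.

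Regions numbered 9, 9, 4, 4, 6, 3 and 4 in the same order. Resolution 1.0 gave 18, 17, 10, 13, 14, 10 and 12. Resolution 0.3 gave 5 in CMM, 4 in CMS, 1 in Colonmix and 2 in SPFIBD. Leaving out mitochondrial, ribosomal protein and ribosomal RNA repeat genes gave 5 in CMM, 3 in IntGF and 2 in SPFIBD.

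The bacterial share relative to another library moved outside the 20 largest mouse features, where those features took differing parts of the counts. Colonmix over ColonGF moved from 62.9 to 113.7-fold, CMM over ColonGF from 129.6 to 114.9, CMS over ColonGF from 159.9 to 141.4, and Colonmix over IntGF from 202.4 to 125.2. Colonmix was 2.54-fold lower than CMS and moved to 1.25-fold lower (a ratio of 0.7995). IntGF over ColonGF moved from 0.311 to 0.954 and SPFIBD over SPF from 0.590 to 0.209.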

Other observations

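In CMM, CMS, Colonmix, SPF and SPFIBD, the 10% of spots with the highest bacterial share had lower goblet cell and mucus genes than the other spots of the same section. Within mouse counts outside the 20 largest features, the list was at a log2 ratio of -0.61 (-0.82 to -0.40) in CMM, -0.32 (-0.45 to -0.18) in CMS, -0.69 (-0.82 to -0.57) in Colonmix, -0.44 (-0.52 to -0.36) in SPF and -0.37 (-0.48 to -0.26) in SPFIBD. The sum leans on Muc2, and without it, an alternative chosen after seeing the data, the list was at -0.51 (-0.76 to -0.26), -0.13 (-0.34 to 0.08), -0.73 (-0.94 to -0.52), -0.71 (-0.91 to -0.51) and -0.18 (-0.34 to -0.02). The list was not alone: in Colonmix, antimicrobial genes were at -0.79 (-0.96 to -0.63) and mitochondrially encoded genes at -0.70 (-0.76 to -0.64), and in SPF absorptive genes at -0.73 (-0.86 to -0.60). Over all spots, which are not independent replicates, the relation was weak and did not keep this sign. Spearman's correlation of the list with the bacterial share was -0.210 in CMM and -0.059 in CMS, but 0.104 in Colonmix, 0.097 in SPF and 0.073 in SPFIBD. With channel means removed it was -0.238, -0.208, -0.062, -0.154 and -0.101. The spots of highest share in ColonGF (-0.37, -0.41 to -0.33) and IntGF (-0.28, -0.36 to -0.21) were lower in the list by about as much as those of CMS, SPF and SPFIBD, although they held only 1.70 and 1.71 bacterial counts each. Spots of highest share also held fewer counts in all, with medians of 831 against 1772 in ColonGF, 2138 against 5303 in Colonmix, 1833 against 5194 in SPF and 1293 against 3147 in SPFIBD, so the lower list is not separated from spot depth.

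B and plasma cell genes were lower in the spots of highest bacterial share in SPFIBD (-1.10, -1.42 to -0.80), CMS (-1.06, -1.70 to -0.48), Colonmix (-1.09, -1.59 to -0.63) and SPF (-0.55, -1.11 to -0.04), but not in CMM (0.06, -0.47 to 0.54). In SPFIBD and Colonmix most counts of this list are those of Igha, and without it the list was at -0.38 (26 against 570 counts, with an interval that includes 0) and -0.75 (-1.46 to -0.12); in CMM, CMS and SPF too few counts were left. Spearman's correlation over all spots was -0.291, -0.137, -0.175, -0.177 and -0.061 in that order of libraries. Absorptive colonocyte and smooth muscle genes went differing ways between libraries and between both measures: smooth muscle genes were lower in such spots of Colonmix (-0.72, -0.84 to -0.61) and SPF (-0.14, -0.25 to -0.04), whereas the correlations over all spots were 0.116 and 0.146.

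Smooth muscle genes were lower in SPFIBD than in SPF. The tests of the length trend and of a smaller muscle area were chosen after the result was seen; those of absent muscle and of DNA dilution were set before their values. A trend of ratios with gene length does not produce it, as the list stayed at percentile 0 with the trend removed, and dilution by DNA does not either (percentile 0 among lists matched on counts per kb). To ask about muscle area, spots were ranked by a random part of the list and the rest of the list was measured in the 10% of spots ranked highest, over 50 random splits of the list. The median ratio there was -2.90, from -3.50 to -2.48 over the splits, against -2.56 for the whole section. Muscle was not absent, since the rest of the list was enriched 1.72-fold in such spots of SPFIBD (median, with 1.47 as the lowest and 1.84 as the highest of the splits). Enrichment in SPF was 2.20-fold, so the spots ranked highest were less enriched in SPFIBD, for a reason that was not tested. Muscle of equal level over a smaller area therefore cannot be told apart from lower muscle transcript levels.

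Bacterial counts gathered in part of the sections of CMM, CMS, Colonmix, SPF and SPFIBD. The tests of channels, of mouse counts and of the first set of prefixes were chosen after the result was seen, and that of the second set before. Chip channels alone do not make the pattern, since the lowest Moran's I was 0.382 and the highest 0.676 with channel means removed. Fewer mouse counts would raise the share, and spot totals were lower where the share was highest (a median of 2138 against 5303 counts in Colonmix and 1833 against 5194 in SPF). Bacterial counts beyond a straight-line relation with mouse counts, on log scales, still had a Moran's I of 0.448 to 0.636 with channel means removed. Fewer mouse counts alone therefore could not make the pattern. The value of IntGF, 0.048, rests on 1111 bacterial counts and is no matched reference. For the first set, the share of ColonGF was at most 0.0159 of that of Colonmix, CMM or CMS, and that of IntGF 0.00494 of that of Colonmix. Mouse reads on bacterial features were thus few in ColonGF and IntGF. ColonGF lacks many mouse features, and counts of both followed gene length less (0.152 and 0.305). No upper limit therefore follows for the other libraries. For the second set, 0 libraries labelled GF were counted, and mouse reads on bacterial features cannot be told apart from bacteria.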
